A study of Mus musculus with 10 samples.

How the data were processed

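Bone marrow-derived mast cells of wild-type C57BL/6 mice were lysed in TCL buffer, per the labels' protocols. RNA was purified on SPRI beads and turned into full-length cDNA by template switching (SmartSeq2). After preamplification, Nextera XT libraries were sequenced on a NextSeq500 as 2 x 38 base pairs. The protocol names no molecular identifiers. Per the submitters' processing notes, STAR, HTSeq and DESeq2 were used with GRCm38 (mm10); their versions and the annotation release are not given in the sources used here. The deposited values are the authors' read counts per gene, in the unit count, together with counts of reads without a feature, ambiguous between genes or not uniquely aligned. The values were whole numbers, as that unit requires.

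The table held 49671 gene rows, of which 49326 carried a symbol, and 5 further rows that named no gene. Loci were taken from GENCODE vM21 on GRCm38. Counts assigned to genes ranged from 1237382 to 2323916 per library (median 1708100), 16.4% to 26.6% of all counted reads or alignments (6041990 to 9323495). Of these, 37.2% to 55.6% were not uniquely aligned, 26.0% to 33.6% had no feature and 2.05% to 2.85% were ambiguous. Loci overlapping ribosomal RNA took 10.8% to 15.6% of gene counts, and loci overlapping satellite repeats 3.02% to 14.3%. A level of 3 counts corresponded to 1.26 to 2.55 CPM. Where a control group had 0 counts, a change is given as at least the fold over 3 counts in the group; with 1 to 3 counts, as a pooled count ratio with a 95% counting interval. Between replicates the chi-square per gene was 3.30 to 4.24, above the 1 of pure counting error, and the Pearson correlation of log CPM was 0.955 to 0.968.

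Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F tests). The model had 1 mean for each of the 6 groups over all 10 libraries, which left 4 residual degrees of freedom, and the common biological coefficient of variation was 0.126. The filter kept 11247 genes. The 2 groups of TGF-β alone had 1 library each, and their spread was taken from the other groups. The 7 contrasts were SCF against IL-3, SCF with 1 and with 10 ng/mL TGF-β against SCF, the 2 doses against each other, TGF-β alone (mean of both doses) against IL-3, SCF with TGF-β against TGF-β alone (means of both doses), and the interaction of TGF-β and SCF on the log2 scale. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each contrast. The columns were not assigned by anything beyond the labels, and no column was left out. No contrast compared sides of at least 3 libraries each, so group labels were not permuted, and no group had the 4 libraries that the test for outlying libraries needs.

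Gene lists were written before the files were examined: 25 lists with 434 genes, of which 3 symbols were absent from the table and 290 genes passed the filter. They cover mucosal, connective tissue, identity, granule and amine, eicosanoid, cytokine and chemokine, TGF-β response, integrin, cell cycle, MAPK feedback and immediate early, STAT5 and survival, cholesterol synthesis, glycolysis and hypoxia, unfolded protein and amino acid response, interferon-stimulated, and sialyl and glycan transfer genes, markers of basophils, macrophages, neutrophils, eosinophils, lymphocytes, dendritic cells, erythroid cells and platelets, and fibroblasts, and RNA quality and stress genes. The 18 lists with at least 5 tested members were tested with camera in limma 3.58.1, at a preset correlation of 0.01 and at an estimated one. Members past the threshold are counted with the adjustment over all genes and over the list alone. The named genes followed a rule also written beforehand: 10 anchor genes in every comparison, the 8 largest rises and falls per comparison among called genes with a mean of at least 20 CPM in a compared group and every library of one side beyond the other (this last not for the interaction), without predicted genes, clones and pseudogenes, and up to 4 called members per list. This selected 75, 58, 70, 12, 51, 86 and 27 genes in the order of the contrasts above, of which the text gives a subset. Some of the selected genes are not reported.

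The alternatives were DESeq2 size factors, DESeq2 1.42.0 (Wald test), limma-voom, no filter except genes with 0 counts throughout, a filter of 10 CPM in at least 2 libraries, an added 2-fold threshold, a fit of only the groups compared, a replicate block, each library left out in turn, and for the lists the estimated correlation, the replicate block and no filter. Chosen after the data were seen were fits without the ribosomal RNA and satellite loci, without both TGF-β alone libraries, and without the second libraries of the 3 SCF-containing groups, and for the overlap of the 2 doses a fit with each dose against a different SCF library (3 residual degrees of freedom). The overlap of the 2 doses was set against 20 simulations of unchanged groups sharing the SCF libraries. The pipeline was tested on simulated data with 200 changed genes in 5 simulations: it recovered 48.0% of 2-fold and 83.2% of 4-fold changes for SCF against IL-3 (5.13% of calls false), 43.2% and 78.6% for TGF-β alone against IL-3 (4.09%), and 22.4% and 66.6% for the interaction (8.02%). Raw reads were not analysed here.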

Results

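Gene expression was measured in bone marrow-derived mast cells (BMMCs), which are mast cells grown out of mouse bone marrow in interleukin 3 (IL-3). The cells came from wild-type C57BL/6 mice. After 6 to 8 weeks in IL-3 they were kept in IL-3 alone, or were stimulated for 72 h with stem cell factor (SCF, the ligand of the receptor KIT), with transforming growth factor beta (TGF-β), or with both. The 10 full-length SmartSeq2 libraries formed 6 groups: IL-3 alone (n = 2), SCF at 100 ng/mL (n = 2), SCF with 1 ng/mL TGF-β (n = 2), SCF with 10 ng/mL TGF-β (n = 2), and TGF-β without added SCF at 1 ng/mL and at 10 ng/mL, with 1 library for each dose. The labels give IL-3 as 5 ng/mL in the growth protocol and as 10 ng/mL in the sample source, give no SCF dose for the combinations and no time for the IL-3 group. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, whatever its source. Reads counted to genes ranged from 1237382 (10 ng/mL TGF-β alone) to 2323916 (replicate 1 of SCF with 1 ng/mL TGF-β), with a median of 1708100. At these depths 3 counts corresponded to 1.26 to 2.55 CPM, a count scaled to library size. Intervals and floors given here cover counting error only, because PCR reads without molecular identifiers are not independent molecules. On the first principal component (50.2% of the variance) the 6 libraries with SCF scored 3.49 to 27.9 and the 4 without it -34.2 to -21.6. On the second (22.4%) the 6 libraries with TGF-β scored -21.2 to -5.37 and the 4 without it 12.2 to 24.98. Values below are log2 fold changes ± standard error, with Benjamini-Hochberg adjusted p-values from edgeR's quasi-likelihood test, or mean CPM ± SD. That test gives no standard error, so it was approximated as the size of the log2 fold change over the square root of the test's F. Of 109 counts of 1 to 3 members of a gene list past the threshold over all genes, 76 moved by over 1.5 times in at least 1 fit without 1 library, 51 of them to 0, so such counts are descriptive. For larger counts each such library is given.

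The mast cell proteases are the products by which mouse mast cell subtypes are usually told apart, with Mcpt1, Mcpt2 and the integrin Itgae as genes of mucosal mast cells. The chymase genes lie close together on chromosome 14 of GRCm38: Cma1 (ENSMUSG00000022225; chromosome 14, 55941451 to 55944675), Cma2 (ENSMUSG00000068289; chromosome 14, 55950980 to 55974031), Mcpt1 (ENSMUSG00000022227; chromosome 14, 56017971 to 56020384), Mcpt2 (ENSMUSG00000022226; chromosome 14, 56042041 to 56044642) and Mcpt4 (ENSMUSG00000061068; chromosome 14, 56059629 to 56062313), with the granzyme B gene Gzmb (ENSMUSG00000015437; chromosome 14, 56258838 to 56262260) in the same cluster. The tryptase genes Tpsab1 (ENSMUSG00000024173; chromosome 17, 25343245 to 25345562) and Tpsb2 (ENSMUSG00000033825; chromosome 17, 25366305 to 25369098) lie together, while carboxypeptidase Cpa3 (ENSMUSG00000001865; chromosome 3, 20215620 to 20242181), integrin Itgae (ENSMUSG00000005947; chromosome 11, 73090583 to 73147446) and receptor Kit (ENSMUSG00000005672; chromosome 5, 75574916 to 75656722) lie elsewhere. All are annotated as protein coding. The chymases, the 2 tryptases, Cyp4a12a with Cyp4a12b, and Mrgprb1 with Mrgprb2 are close paralogs whose shared reads the counting could not split, so their levels are uncertain to that extent.

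The first comparison asked what SCF changed in BMMCs already growing in IL-3. The granule tryptase Tpsb2 rose from 7952 ± 656 CPM to 16667 ± 2182 CPM (SD, n = 2 libraries per group), a log2 fold change of 1.07 ± 0.13 (adjusted p = 0.000101), and the mast cell carboxypeptidase Cpa3 rose by 0.69 ± 0.12. The mucosal proteases stayed low: Mcpt2 stood at 11.6 ± 2.47 CPM with IL-3 and 21.2 ± 0.286 CPM with SCF (0.89 ± 0.36, adjusted p = 0.143), and Mcpt1 had 0 counts over the IL-3 libraries and 1 over the SCF libraries, so that any difference was not detectable at this depth. Of the 4 tested mucosal mast cell genes 1 was higher at an unadjusted p under 0.05, and none passed over all genes or adjusted over the list alone. The chymase Cma1 (0.03 ± 0.14), the SCF receptor Kit (-0.17 ± 0.12), the IgE receptor chain Fcer1a (0.02 ± 0.11), the inhibitory SMAD gene Smad7 (-0.10 ± 0.57), Itgae (3 counts in each group) and the chymase Mcpt4 (2.03 ± 0.65, adjusted p = 0.0599) did not pass the test. Signs turned without SCF replicate 1 for Cma1 (-0.14), Fcer1a (-0.04) and Smad7 (0.29), and without IL-3 replicate 2 for Cma1 (-0.03) and Smad7 (0.37). Outside the protease genes, the lysosomal glycoprotein Cd68 (4.23 ± 0.52), the metabotropic glutamate receptor Grm6 (3.49 ± 0.33), the nucleobase transporter Slc43a3 (2.94 ± 0.37) and the lectin Clec10a (2.93 ± 0.37) were among the largest rises. Among the largest falls were the fatty acid hydroxylase Cyp4a12b (-4.04 ± 0.27), the metalloproteinase inhibitor Timp3 (-3.57 ± 0.39), the surface glycoprotein Cd24a (-3.44 ± 0.37) and Pigz, a mannosyltransferase of the glycosylphosphatidylinositol anchor (-2.95 ± 0.29).

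Cell cycle genes rose with SCF: 26 of 36 tested members passed the test over all genes and 34 when adjusted over the list alone, all of them upward, with cyclin Ccnb2 at 2.02 ± 0.25, the anaphase activator Cdc20 at 1.90 ± 0.25 and the proliferation marker Mki67 at 1.70 ± 0.27. Camera on the cell cycle list gave adjusted p = 1.39e-36, and adjusted p = 0.180 with an estimated correlation. Cholesterol synthesis genes rose as well, 19 of 24 (21 adjusted over the list alone), including the lanosterol demethylase Cyp51 (1.48 ± 0.18) and squalene epoxidase Sqle (1.03 ± 0.15). Camera on the cholesterol list gave adjusted p = 1.30e-22, and adjusted p = 0.180 with an estimated correlation. In the granule list 7 of 16 rose and 2 fell (7 and 2 adjusted over the list alone), with the lysosomal protease Ctsb at 1.12 ± 0.13, the granule protease Ctsg at 1.89 ± 0.25 and the granule proteoglycan Srgn at 0.70 ± 0.11. Camera on the granule list gave adjusted p = 0.000294, and adjusted p = 0.180 with an estimated correlation. Of the connective tissue mast cell genes 4 of 10 rose and 1 fell (5 and 1 adjusted over the list alone). Camera on the connective tissue list gave adjusted p = 0.00288, and adjusted p = 0.180 with an estimated correlation. Glycolysis and hypoxia genes included 5 of 23 that rose (7 higher and 1 lower adjusted over the list alone), among them pyruvate kinase Pkm (1.09 ± 0.14) and lactate dehydrogenase Ldha (0.83 ± 0.14). Camera on the glycolysis list gave adjusted p = 0.00493, and adjusted p = 0.201 with an estimated correlation. In the unfolded protein and amino acid response list 6 of 17 rose (8 adjusted over the list alone). Camera on the unfolded protein list gave adjusted p = 0.000144, and adjusted p = 0.180 with an estimated correlation. Without IL-3 replicate 2 edgeR called 9 cell cycle, 6 cholesterol, 2 connective tissue, 3 glycolysis and 0 unfolded protein genes higher. Leaving out SCF replicate 1 gave 8 glycolysis genes higher. The fit without SCF replicate 2 called 13 cell cycle and 1 unfolded protein genes higher.

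Signalling genes were followed next. The MAP kinase phosphatase Dusp4 (2.43 ± 0.23), the transcription factor Etv5 (2.40 ± 0.28) and the Ras pathway inhibitor Spred1 (1.28 ± 0.21) rose, the 3 of 22 MAPK feedback and immediate early genes past the threshold (3 higher and 2 lower adjusted over the list alone). Camera on the MAPK list gave adjusted p = 0.0484, and adjusted p = 0.617 with an estimated correlation. All 8 immediate early genes examined, such as Fos at 370.4 CPM in SCF replicate 1 and 202 in SCF replicate 2, were higher in replicate 1 than in replicate 2 in each of the 4 replicated groups. The survival kinase Pim2 fell (-2.24 ± 0.29) with 4 of 15 STAT5 and survival genes (2 higher and 4 lower adjusted over the list alone). Camera on the STAT5 list gave adjusted p = 0.0176, and adjusted p = 0.384 with an estimated correlation. Of the cytokine and chemokine genes 3 of 14 rose, with Tnf at 2.30 ± 0.26 and the monocyte chemoattractant Ccl7 at 1.54 ± 0.19, and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.274). Eicosanoid genes had 2 of 11 higher (4 higher and 1 lower adjusted over the list alone), and sialyl and glycan transfer genes had 2 of 22 lower (3 adjusted over the list alone). Camera gave these lists adjusted p = 0.0384 and 0.0296, and 0.180 for each with an estimated correlation. Without a filter on low counts, camera's adjusted p was 0.300 for the MAPK list, 0.210 for the STAT5 list, 0.300 for the eicosanoid list and 0.210 for the glycan list. The mast cell identity (2 of 16 higher and 2 lower, 3 and 4 adjusted over the list alone), TGF-β response (1 of 21 lower, 2 higher and 4 lower adjusted over the list alone), integrin (1 of 12 higher, 3 adjusted over the list alone) and interferon lists (1 of 12 higher and 1 lower, 1 and 1 adjusted over the list alone) did not pass camera's test. Without IL-3 replicate 1 or IL-3 replicate 2 edgeR called 2 STAT5 and 0 glycan genes lower. Leaving out SCF replicate 1 gave 1 glycan gene lower. The fit without SCF replicate 2 called 1 STAT5 and 0 glycan genes lower.

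In all, 1031 of 11247 tested genes differed between SCF and IL-3, 642 higher and 389 lower, and 506 of them differed at least 2-fold. DESeq2 called 471, the fit without IL-3 replicate 2 called 237, the fit without SCF replicate 2 called 316, and the fit without the second libraries of the 3 SCF-containing groups called 594.

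The next comparisons asked what TGF-β changed in cells that also received SCF. Mcpt2 rose from 21.2 ± 0.286 CPM with SCF to 3327 ± 639.6 CPM with SCF and 1 ng/mL TGF-β and 5384 ± 1888 CPM with SCF and 10 ng/mL (SD, n = 2 libraries per group). The log2 fold changes were 7.29 ± 0.26 (adjusted p = 1.88e-11) and 7.98 ± 0.27 (adjusted p = 5.69e-12). Mcpt1 went from 1 count over both SCF libraries to 76.8 ± 18.8 and 163 ± 68.8 CPM, pooled count ratios of 283-fold (95% counting interval 50.5 to 11230) and 602-fold (95% counting interval 108 to 23810). Itgae, the αE integrin chain CD103, rose 32.96-fold (95% counting interval 10.99 to 162) at 1 ng/mL, where limma-voom's adjusted p was 0.085, and 96.3-fold (95% counting interval 32.7 to 469.6) at 10 ng/mL, while its partner chain Itgb7 fell by 1.14 ± 0.14 and 0.99 ± 0.14 on the log2 scale. These made 3 of 4 tested mucosal mast cell genes higher and 1 lower at each dose, with the same counts adjusted over the list alone. Without a filter this list, too small for camera under the filter, passed at both doses (camera adjusted p = 0.00911 and 0.00744). The tryptase Tpsab1 rose (3.70 ± 0.28 and 3.93 ± 0.28), whereas Tpsb2 (-0.03 ± 0.13 and -0.07 ± 0.13), Cma1 (-0.23 ± 0.14 and -0.25 ± 0.14) and Mcpt4 (1.23 ± 0.42 and 1.16 ± 0.43) did not pass the test. Tpsb2 turned positive without SCF replicate 1 (0.11 and 0.07), and without replicate 2 of the compared group (0.10 and 0.03). Cpa3 fell from 25131 ± 2271 CPM with SCF to 12565 ± 1648 and 10351 ± 353 CPM (adjusted p = 5.24e-05 and 2.48e-06). Granzyme B, Gzmb, fell from 1763 ± 98.5 CPM with SCF to 160.1 ± 16.2 and 55.3 ± 16.96 CPM (-3.46 ± 0.22 and -5.004 ± 0.24, adjusted p = 6.86e-08 and 9.17e-10).

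**Figure D1:**
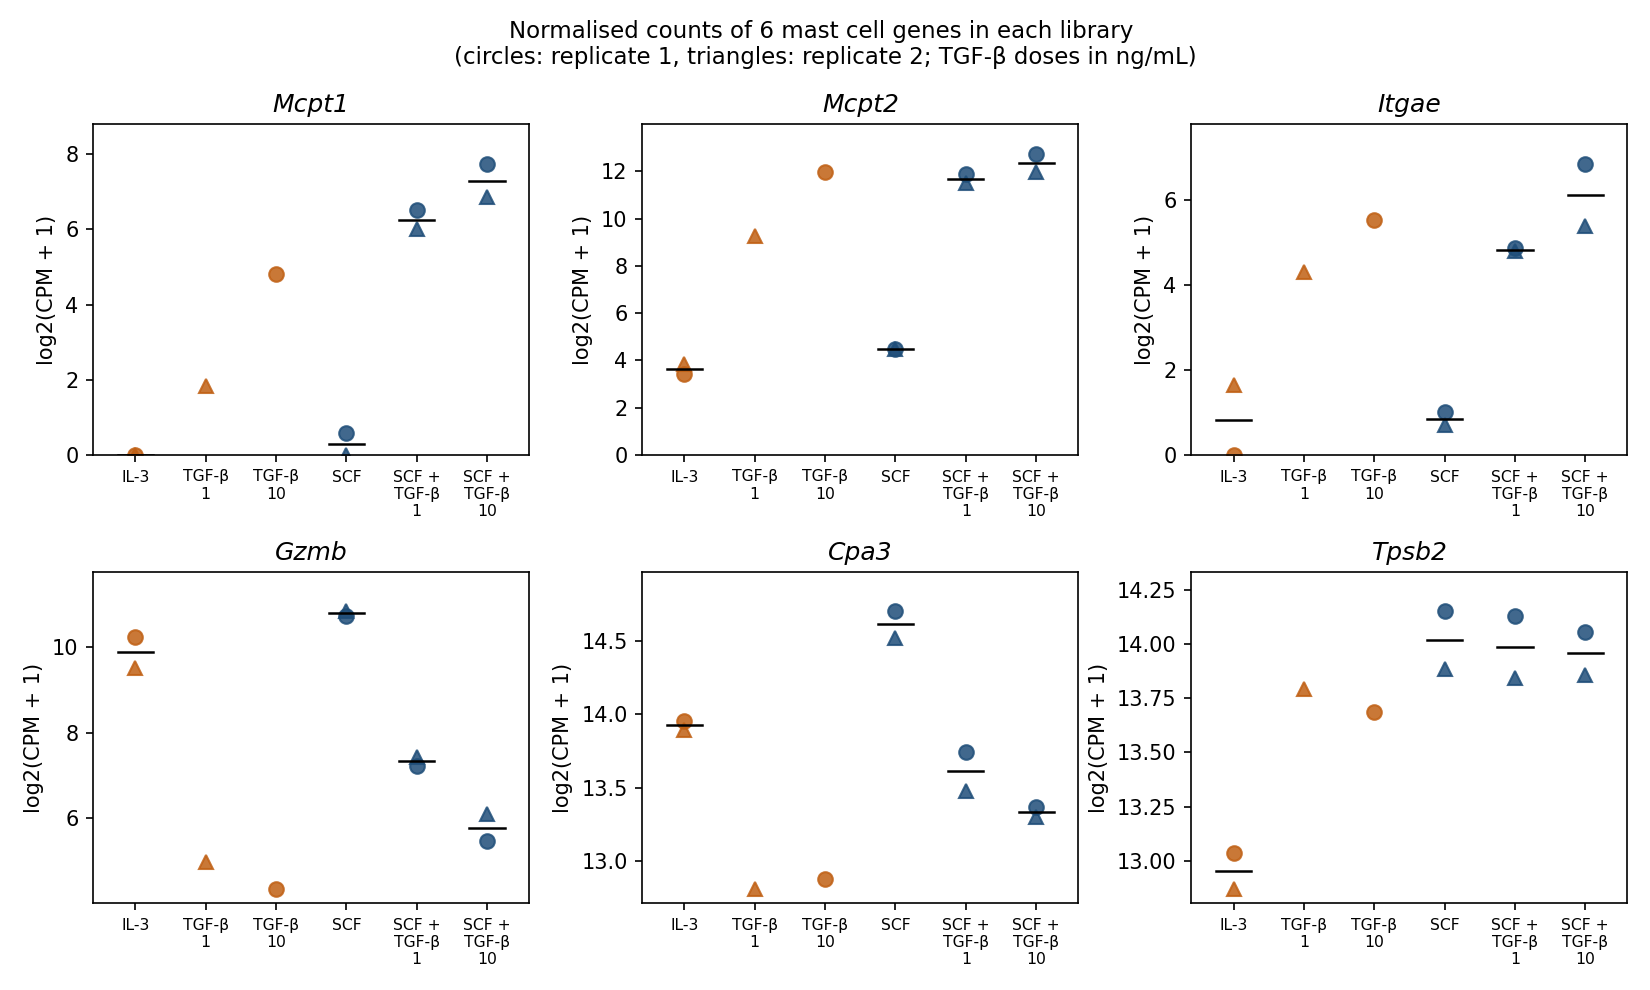
Normalised counts of 6 mast cell genes in the 10 libraries, as log2(CPM + 1) on the vertical axis against group on the horizontal axis, with circles for replicate 1, triangles for replicate 2, blue for groups with SCF, orange for groups without it and black bars for the means of groups of 2; only the top panels start at 0. Mcpt2 averaged 21.2 CPM with SCF and 5384 CPM with SCF and 10 ng/mL TGF-β, while Gzmb averaged 1763 and 55.3 CPM.

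Genes of the TGF-β pathway responded at both doses. The SMAD repressor Skil rose by 3.42 ± 0.25 and 3.97 ± 0.24, the TGF-β signalling inhibitor Ldlrad4 by 3.67 ± 0.63 and 4.56 ± 0.57, and Smad7 by 1.79 ± 0.45 and 2.87 ± 0.40. The 1 ng/mL value of Smad7 (adjusted p = 0.0265) was not past the threshold with DESeq2 (adjusted p = 0.16), limma-voom (0.070), the 2 groups alone (0.055), any of the 4 fits without an SCF or SCF with 1 ng/mL TGF-β library (0.052 to 0.26) or the fit without the second libraries (0.060). At 10 ng/mL the helix-loop-helix gene Id3 rose too (2.68 ± 0.32), and its relative Id2 fell at 1 ng/mL (-0.78 ± 0.13). In the TGF-β response list 5 of 21 rose and 1 fell at 1 ng/mL (5 and 3 adjusted over the list alone), and 6 rose and 2 fell at 10 ng/mL (10 and 4 adjusted over the list alone). The TGF-β response list at 1 ng/mL had a camera adjusted p = 0.000460, and adjusted p = 0.296 with an estimated correlation. TGF-β response genes at 10 ng/mL had a camera adjusted p = 1.06e-06, and adjusted p = 0.250 with an estimated correlation. Without SCF replicate 1, SCF replicate 2, replicate 1 of SCF with 1 ng/mL or replicate 2 of SCF with 1 ng/mL edgeR called 3 TGF-β response genes higher at 1 ng/mL. Integrin genes moved both ways, 3 of 12 higher and 2 lower at 1 ng/mL and 3 and 2 at 10 ng/mL (adjusted over the list alone 3 and 2, then 3 and 3). The laminin receptor chain Itga7 had 0 counts with SCF and was at least 13.8-fold and at least 28.99-fold higher with TGF-β, against a floor of 3 counts over the group. The leukocyte integrin chain Itgb2 fell (-1.63 ± 0.28 and -2.54 ± 0.31). The adhesion receptor Adgra1 was among the largest rises (pooled count ratios of 154-fold (95% counting interval 27.4 to 6137) and 360.2-fold (95% counting interval 64.3 to 14260)). Among the largest falls were the orphan receptor Gpr176 (-3.07 ± 0.28 and -3.44 ± 0.29) and Clec10a (-3.49 ± 0.38 and -4.14 ± 0.41). The secretagogue receptor Mrgprb2, a gene of connective tissue mast cells, also fell (-2.69 ± 0.39 and -2.62 ± 0.39).

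The next lists hold granule and mediator genes. In the granule list 6 of 16 fell and 1 rose at 1 ng/mL (8 and 1 adjusted over the list alone), and 8 fell and 1 rose at 10 ng/mL (9 and 2 adjusted over the list alone), with the histamine-forming enzyme Hdc at -2.03 ± 0.24 and -1.82 ± 0.23 and Srgn at -0.90 ± 0.11 and -1.06 ± 0.11. For the granule list at these doses camera gave adjusted p = 7.45e-09 and 7.73e-10, and 0.137 and 0.118 with an estimated correlation. Mast cell identity genes fell in 4 and 7 of 16 cases and rose in 1 (7 and 7 lower and 1 higher adjusted over the list alone). The identity list at 1 and 10 ng/mL had camera adjusted p = 0.000497 and 0.000361, and 0.296 and 0.259 with an estimated correlation. Fcer1a fell by 0.65 and 0.88 on the log2 scale, the first not past the threshold without replicate 2 of SCF with 1 ng/mL TGF-β (adjusted p = 0.060). Kit stood at -0.41 ± 0.12 (adjusted p = 0.0583) and -0.42 ± 0.12 (adjusted p = 0.0356), and the second of these was not past the threshold in 8 alternatives (adjusted p = 0.051 to 0.29), including 3 of the 4 fits without an SCF or SCF with 10 ng/mL TGF-β library. Cytokine and chemokine genes fell in 5 and 7 of 14 cases and rose in 1 (7 and 8 lower and 1 higher adjusted over the list alone). At 1 and 10 ng/mL camera gave the cytokine list adjusted p = 1.57e-06 and 2.39e-08, and 0.184 and 0.125 with an estimated correlation. The chemokines Ccl2 (-1.35 ± 0.14 and -1.77 ± 0.14) and Ccl7 (-1.34 ± 0.19 and -1.52 ± 0.19) and the cytokine oncostatin M, Osm (-1.28 ± 0.21 and -1.48 ± 0.22), were among them. Leukotriene C4 synthase Ltc4s fell at 10 ng/mL (-1.91 ± 0.29) while cyclooxygenase Ptgs1 rose (0.87 ± 0.16 and 0.96 ± 0.16), and the eicosanoid list as a whole split 2 higher to 2 lower of 11 at each dose (3 and 3, then 2 and 2, adjusted over the list alone). Leaving out SCF replicate 1 gave 4 identity and 4 cytokine genes lower at 10 ng/mL. The fit without replicate 2 of SCF with 1 ng/mL called 2 identity genes lower at 1 ng/mL. Without replicate 1 of SCF with 10 ng/mL or replicate 2 of SCF with 10 ng/mL edgeR called 4 identity genes lower at 10 ng/mL.

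Glycolysis and hypoxia genes fell in 4 of 23 cases at 1 ng/mL, with 1 higher (8 and 1 adjusted over the list alone), and in 6 at 10 ng/mL (8 adjusted over the list alone). At 1 and 10 ng/mL camera gave the glycolysis list adjusted p = 3.30e-06 and 2.23e-07, and 0.184 and 0.125 with an estimated correlation. The glucose transporter Slc2a3 (-1.22 ± 0.15 and -1.46 ± 0.15), Pkm (-0.93 ± 0.14 and -1.19 ± 0.14) and the stress-responsive gene Ndrg1 (-2.07 ± 0.22 and -2.19 ± 0.23) led this list. Cell cycle genes rose further than with SCF alone, in 10 and 20 of 36 cases (33 and 31 adjusted over the list alone), for example thymidylate synthase Tyms (1.21 ± 0.19 at 10 ng/mL) and the helicase subunit Mcm6 (0.87 ± 0.15). For the cell cycle list at these doses camera gave adjusted p = 8.30e-20 and 9.46e-19, and 0.296 and 0.262 with an estimated correlation. STAT5 and survival genes fell in 4 and 5 of 15 cases (5 and 5 adjusted over the list alone), with the interleukin 2 receptor chain Il2ra at -1.75 ± 0.33 and -2.28 ± 0.35. The STAT5 list at 1 and 10 ng/mL had camera adjusted p = 0.00475 and 0.00570, and 0.331 and 0.310 with an estimated correlation. Of 17 unfolded protein and amino acid response genes 5 fell at 10 ng/mL (5 adjusted over the list alone), and at 1 ng/mL 4 were lower at an unadjusted p under 0.05 with none past the adjusted threshold. The unfolded protein list at 1 ng/mL had a camera adjusted p = 0.0373, and adjusted p = 0.424 with an estimated correlation. Unfolded protein genes at 10 ng/mL had a camera adjusted p = 0.00940, and adjusted p = 0.310 with an estimated correlation. The sialyltransferase St3gal1 (-1.66 ± 0.27 and -1.53 ± 0.27) fell at both doses. In the glycan list 2 of 22 fell at 1 ng/mL (3 adjusted over the list alone), and 3 fell and 1 rose at 10 ng/mL (5 and 1 adjusted over the list alone; camera adjusted p = 0.0672). The glycan list at 1 ng/mL had a camera adjusted p = 0.0373, and adjusted p = 0.274 with an estimated correlation, and adjusted p = 0.116 without a filter. Connective tissue mast cell genes fell in 4 and 5 of 10 cases and rose in 1 (5 and 5 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.124 at 1 ng/mL). Connective tissue genes at 10 ng/mL had a camera adjusted p = 0.0337, and adjusted p = 0.259 with an estimated correlation. Cholesterol synthesis genes fell in 1 of 24 cases at 10 ng/mL (1 adjusted over the list alone), and at 1 ng/mL 2 were lower at an unadjusted p under 0.05 (camera adjusted p = 0.305). Cholesterol genes at 10 ng/mL had a camera adjusted p = 0.00512, and adjusted p = 0.462 with an estimated correlation. The MAPK list (1 lower at 1 ng/mL, 1 higher and 1 lower at 10 ng/mL, of 22; adjusted over the list alone 1 and 1, then 3 and 2) and the interferon list (1 of 12 lower at 10 ng/mL, 1 adjusted over the list alone) did not pass camera's test. Leaving out IL-3 replicate 1 gave 19 cell cycle genes higher at 1 ng/mL. The fit without IL-3 replicate 2 called 18 cell cycle genes higher at 1 ng/mL. Without SCF replicate 1 edgeR called 0 cell cycle genes higher at 1 ng/mL, 2 STAT5 and 2 connective tissue genes lower at 1 ng/mL, 4 cell cycle genes higher at 10 ng/mL and 3 STAT5 and 3 unfolded protein genes lower at 10 ng/mL. Leaving out SCF replicate 2 gave 5 cell cycle genes higher at 1 ng/mL and 0 unfolded protein genes lower at 10 ng/mL. The fit without replicate 2 of SCF with 1 ng/mL called 1 cell cycle gene higher at 1 ng/mL and 2 STAT5 and 2 connective tissue genes lower at 1 ng/mL. Without replicate 1 of SCF with 10 ng/mL edgeR called 10 cell cycle genes higher at 10 ng/mL and 0 unfolded protein genes lower at 10 ng/mL. Leaving out replicate 2 of SCF with 10 ng/mL gave 6 cell cycle genes higher at 10 ng/mL and 1 unfolded protein gene lower at 10 ng/mL.

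**Figure D2:**
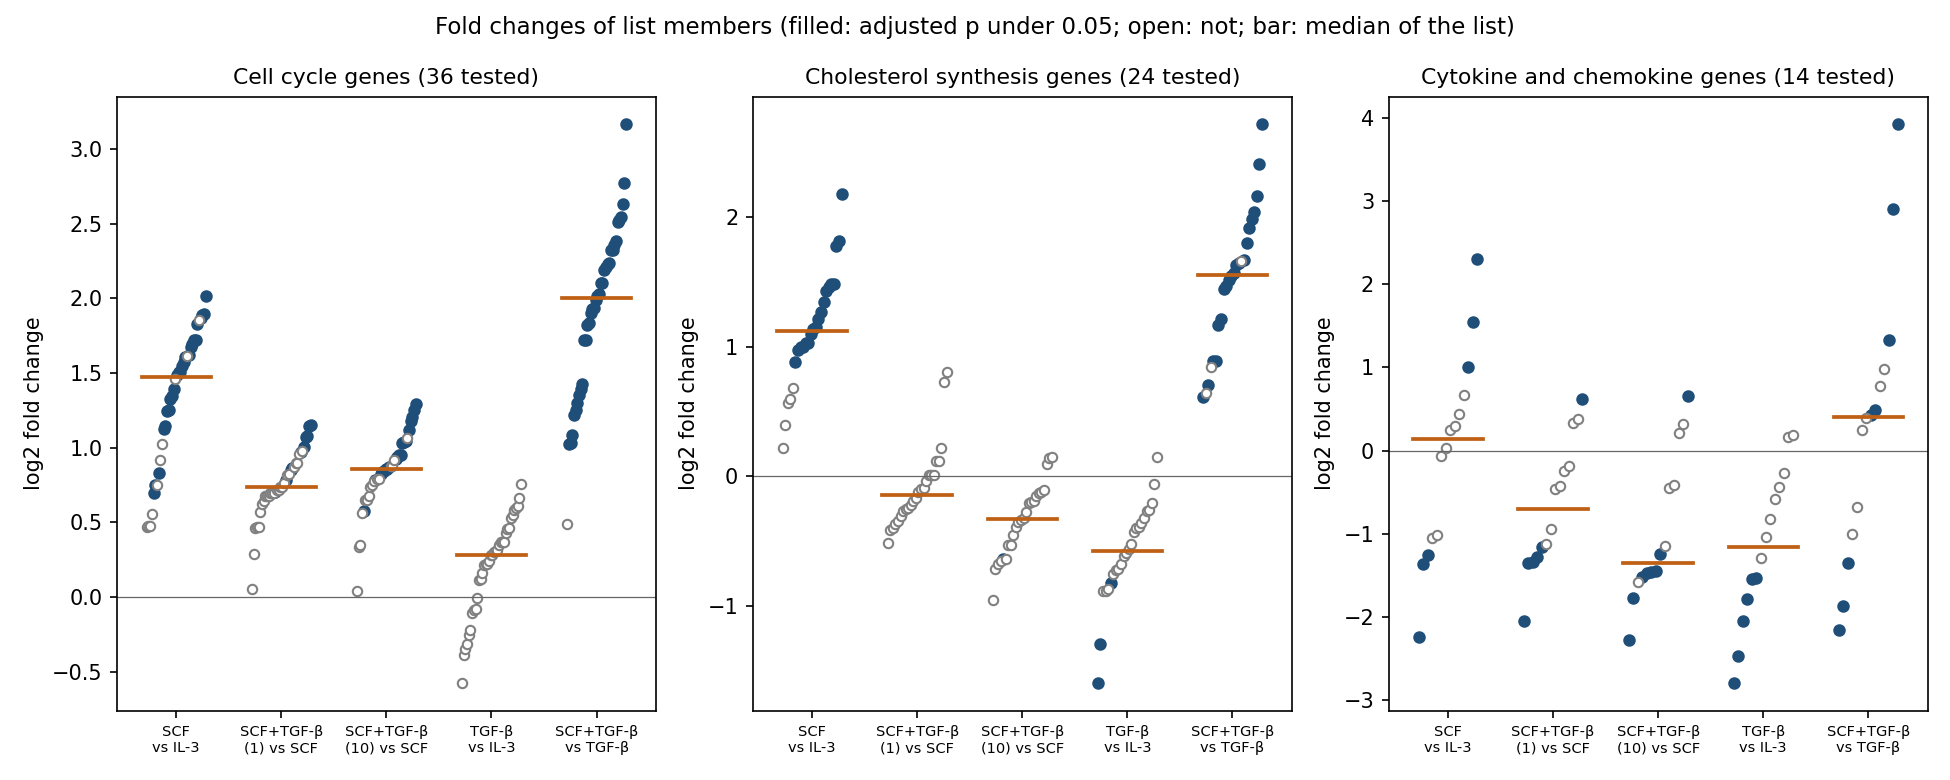
Log2 fold changes (vertical axis) of the tested members of the cell cycle, cholesterol synthesis and cytokine and chemokine lists in 5 comparisons (horizontal axis), 1 point per gene, filled where the adjusted p was under 0.05, with bars at the list medians. Filled points number 26 and 35 of 36 cell cycle genes in the comparisons of SCF with IL-3 and of SCF plus TGF-β with TGF-β, and 6 of 14 cytokine genes lie filled below 0 with TGF-β alone.

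Against SCF, 522 genes differed with 1 ng/mL TGF-β (213 higher, 309 lower, 287 at least 2-fold) and 941 with 10 ng/mL (425 higher, 516 lower, 510 at least 2-fold). DESeq2 called 270 and 438, the fit without the second libraries of the 3 SCF-containing groups called 289 and 559, and the fits without SCF replicate 1 called 252 and 503 and without SCF replicate 2 called 338 and 625. Leaving out replicate 2 of SCF with 1 ng/mL TGF-β gave 253 at that dose, and leaving out replicate 1 or 2 of SCF with 10 ng/mL gave 447 or 531 at the other.

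The dose comparison set SCF with 10 ng/mL TGF-β against SCF with 1 ng/mL. Mcpt1 (1.08 ± 0.25, adjusted p = 1), Mcpt2 (0.69 ± 0.18, adjusted p = 1) and Itgae (1.501 ± 0.36, adjusted p = 1) had positive values that did not pass the test over all genes. All 3 passed when adjusted over the list alone of 4 tested mucosal mast cell genes, and over all genes without replicate 2 of SCF with 10 ng/mL. Without a filter the mucosal list passed (camera adjusted p = 0.0164). Cpa3 (-0.28 ± 0.12), Smad7 (1.08 ± 0.32), Fcer1a (-0.23 ± 0.11), Mcpt4 (-0.07 ± 0.37), Cma1 (-0.02 ± 0.14), Tpsb2 (-0.03 ± 0.13) and Kit (-0.01 ± 0.12) did not pass either. Signs turned in fits without 1 library of these groups for Mcpt4 (0.09 without replicate 1 at 1 ng/mL, 0.36 without replicate 1 at 10 ng/mL) and Kit (0.01 without replicate 2 at 1 ng/mL, 0.04 without replicate 1 at 10 ng/mL). They turned too for Cma1 and Tpsb2, without replicate 1 at 1 ng/mL (0.15 and 0.11) and without replicate 2 at 10 ng/mL (0.13 and 0.07). Id3 rose (1.93 ± 0.30) and Gzmb fell (-1.54 ± 0.23), both at an adjusted p of 0.0349, the 2 genes called. With DESeq2 neither was past the threshold (0 genes, 46 at an unadjusted p under 0.05), nor with limma-voom (0 genes, 306 unadjusted), against 313 unadjusted in edgeR's test. The edgeR counts were 0 as well with the filter at 10 CPM (235 unadjusted), with the 2 groups alone (258), without both TGF-β alone libraries (284), without replicate 1 of SCF with 1 ng/mL TGF-β (366) and without replicate 1 of SCF with 10 ng/mL (278). The count was 1 without either IL-3 library, where Id3 was not past the threshold (adjusted p = 0.0858 and 0.0940), 5 without replicate 2 of SCF with 10 ng/mL, 8 with no filter and 8 without the second libraries. Gzmb was not past the threshold without replicate 2 of SCF with 1 ng/mL TGF-β (adjusted p = 0.123). At both doses 479 genes passed against SCF in the same direction (200 higher, 279 lower). Independent lists of these sizes would share 8.05 and 14.2, and simulated unchanged groups against the same SCF libraries shared 0.20 on average over 20 simulations. The simulation took all libraries as independent. Both comparisons use the same SCF libraries, so these also enter the excess. In a fit chosen after this overlap was seen, each dose was set against 1 SCF library of its own. It shared 241 genes (90 higher, 151 lower) with SCF replicate 1 as the control of 1 ng/mL and 202 (75 and 127) with the controls exchanged, where independent lists would share 2.59 and 5.75, then 2.23 and 5.28. Across 6393 genes with a mean of at least 20 CPM, which are not independent replicates, the fold changes at the 2 doses correlated at r = 0.929 (0.515 simulated) with a covariance of 0.243 (0.0311 simulated). With separate controls these were 0.710 and 0.216, then 0.707 and 0.216 with the controls exchanged. Of the 522 genes called at 1 ng/mL, 378 (72.4%) had the larger fold change at 10 ng/mL. Camera placed the TGF-β response list higher at 10 ng/mL (1 of 21 past the threshold, 5 adjusted over the list alone) and the cholesterol list lower. Their camera adjusted p was 9.35e-05 and 0.000297, and 0.448 and 0.561 with an estimated correlation. The granule (camera adjusted p = 0.0106, and adjusted p = 0.448 with an estimated correlation), cytokine (camera adjusted p = 0.0106, and adjusted p = 0.477 with an estimated correlation), glycolysis (camera adjusted p = 0.0422, and adjusted p = 0.545 with an estimated correlation) and basophil lists (camera adjusted p = 0.0196, and adjusted p = 0.448 with an estimated correlation) were lower too, but not without a filter (adjusted p = 0.0829, 0.127, 0.191 and 0.278). Adjusted over the list alone, Gzmb in the granule list and 1 integrin gene were the other members past the threshold.

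The fourth comparison asked what TGF-β did without added SCF, as the mean of the 1 and 10 ng/mL libraries against IL-3. Mcpt2 rose from 11.6 ± 2.47 CPM (SD, n = 2) to 604 CPM at 1 ng/mL and 3979 CPM at 10 ng/mL, a log2 fold change of 7.08 ± 0.28 for the mean (adjusted p = 8.40e-11). Mcpt1 had 0 counts with IL-3 and stood at 2.55 and 27.2 CPM, at least 17.2-fold higher against 3 counts over the group. It passed at adjusted p = 0.0425, but not with limma-voom (0.15), without IL-3 replicate 1 (0.19) or 2 (0.14) or without the 10 ng/mL library (0.37). Itgae rose 36.3-fold (95% counting interval 11.98 to 179.7), with adjusted p = 0.00179, but not with limma-voom (0.11), without IL-3 replicate 1 (0.065) or without the 10 ng/mL library (0.050). Its fitted value of 4.91 became 8.69 without IL-3 replicate 2. These made 3 of 4 tested mucosal mast cell genes higher (3 higher and 1 lower adjusted over the list alone), a list that passed without a filter (camera adjusted p = 0.0253). The fit without IL-3 replicate 1 or the 10 ng/mL library called 1 mucosal gene higher. Without the 1 ng/mL library edgeR called 1 mucosal gene lower. Tpsb2 rose (0.78 ± 0.13), Cpa3 fell (-1.08 ± 0.12), and Fcer1a fell (-0.62 ± 0.11), while Cma1 (-0.32 ± 0.14), Kit (-0.25 ± 0.12) and Mcpt4 (1.55 ± 0.74) did not pass the test. Gzmb fell from 962 ± 328 CPM to 30.5 and 19.4 CPM (-5.30 ± 0.27, adjusted p = 2.58e-09). Among the largest changes, Adgra1 was at least 70.3-fold higher, and the galectin Lgals1 (-3.42 ± 0.22) and complement properdin Cfp (-2.86 ± 0.26) fell.

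The library with 1 ng/mL TGF-β alone is a replicate 2 and the library with 10 ng/mL a replicate 1, so their dose cannot be separated from the replicate number. In each of the 4 groups with 2 libraries, 8 of 8 immediate early genes were higher in replicate 1. By dose, with 1 library each and no test, log2 fold changes against IL-3 at 1 and 10 ng/mL were 5.72 and 8.44 for Mcpt2, 4.27 and 5.54 for Itgae, 2.70 and 3.29 for Smad7 and 0.83 and 0.73 for Tpsb2. With SCF present the corresponding values against SCF were 7.29 and 7.98 for Mcpt2, 4.93 and 6.43 for Itgae, 1.79 and 2.87 for Smad7, and -0.03 and -0.07 for Tpsb2. Skil (3.08 ± 0.22), Id3 (2.12 ± 0.30), Smad7 (2.99 ± 0.42) and Ldlrad4 (3.14 ± 0.49) rose, among 6 of 21 TGF-β response genes that rose and 2 that fell (7 and 3 adjusted over the list alone). As a list, TGF-β response genes had a camera adjusted p = 2.09e-06, and adjusted p = 0.226 with an estimated correlation. Cytokine and chemokine genes fell in 6 of 14 cases (6 adjusted over the list alone), with Ccl7 at -2.79 ± 0.31, Ccl2 at -1.55 ± 0.14 and Osm at -1.53 ± 0.23. As a list, cytokine genes had a camera adjusted p = 2.58e-11, and adjusted p = 0.149 with an estimated correlation. The granule list held 5 falls and 2 rises among 16 (7 and 2 adjusted over the list alone), among them Hdc (-1.73 ± 0.25), Srgn (-0.89 ± 0.11) and the tetraspanin Cd63 (0.85 ± 0.11). As a list, granule genes had a camera adjusted p = 2.67e-06, and adjusted p = 0.149 with an estimated correlation. The identity list held 4 falls and 1 rise among 16 (5 and 1 adjusted over the list alone). As a list, identity genes had a camera adjusted p = 0.000198, and adjusted p = 0.226 with an estimated correlation. Cholesterol synthesis genes fell in 3 of 24 cases (6 adjusted over the list alone), with Sqle at -1.29 ± 0.18, and glycolysis and hypoxia genes in 3 of 23 (7 lower and 1 higher adjusted over the list alone), with Slc2a3 at -1.37 ± 0.17. As a list, cholesterol genes had a camera adjusted p = 4.24e-06, and adjusted p = 0.324 with an estimated correlation. As a list, glycolysis genes had a camera adjusted p = 0.00129, and adjusted p = 0.226 with an estimated correlation.

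Cell cycle genes gave no single member past the threshold with TGF-β alone (2 of 36 higher at an unadjusted p under 0.05), although 26 had positive values. As a list, cell cycle genes had a camera adjusted p = 0.00139, and adjusted p = 0.562 with an estimated correlation. STAT5 and survival genes fell in 4 of 15 cases and rose in 1 (6 and 1 adjusted over the list alone). As a list, STAT5 genes had a camera adjusted p = 0.000519, and adjusted p = 0.240 with an estimated correlation. Unfolded protein response genes fell in 1 of 17 cases (3 adjusted over the list alone). As a list, unfolded protein genes had a camera adjusted p = 0.0402, and adjusted p = 0.411 with an estimated correlation. The fucosyltransferase Fut8 fell (-1.41 ± 0.21), as did 2 of 22 glycan transfer genes in all (2 adjusted over the list alone; camera adjusted p = 0.164). The other lists did not pass camera's test: connective tissue genes (2 higher, 2 lower of 10, 2 and 5 adjusted over the list alone), integrins (2 and 1 of 12, 4 and 2 adjusted over the list alone), and eicosanoid genes (1 and 1 of 11, 1 and 1 adjusted over the list alone). Nor did MAPK genes (no member past the threshold, 2 and 2 of 22 adjusted over the list alone) and interferon genes (no member of 12, 1 at an unadjusted p under 0.05). Leaving out IL-3 replicate 1 gave 4 cell cycle genes higher and 1 STAT5 gene lower. The fit without IL-3 replicate 2 called 2 STAT5 genes lower. Without replicate 1 of SCF with 1 ng/mL or replicate 2 of SCF with 1 ng/mL edgeR called 4 connective tissue genes lower. Leaving out the 10 ng/mL library gave 1 STAT5 gene lower. The 1 ng/mL library had 55.6% of all its counted reads not uniquely aligned and 14.3% of its gene counts in satellite loci, and the 10 ng/mL library 45.7% and 7.18%, against 42.7% and 48.8%, and 5.85% and 9.25%, with IL-3. In this comparison 391 genes passed, 153 higher and 238 lower, 228 of them at least 2-fold. With a block for the replicate number 718 passed. The count was 225 with DESeq2, 601 with no filter, 712 with only these groups fitted, 683 without the second libraries of the SCF-containing groups, 179 and 259 without IL-3 replicate 1 and 2, 242 without the 1 ng/mL library and 143 without the 10 ng/mL library.

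The TGF-β responses with and without SCF could be set side by side, since they share no libraries. The 441 genes that rose with TGF-β in SCF (mean of both doses) had positive values with TGF-β alone in 373 cases (84.6%), and 97 of them also passed there. The 601 that fell had negative values in 547 cases (91.0%), and 151 also passed, where independent lists would share 6.00 and 12.7. Mcpt2, Skil, Id3, Gzmb and Cpa3 were among the shared genes. Across 6393 genes with a mean of at least 20 CPM, Pearson's r was 0.614 and Spearman's rho 0.422, and across all 11247 genes 0.441 and 0.326, as a description only, because genes are not independent replicates. Over all genes, r was 0.280 for the 1 ng/mL library (replicate 2) and 0.427 for the 10 ng/mL library (replicate 1), a difference that dose and replicate number share.

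**Figure D3:**
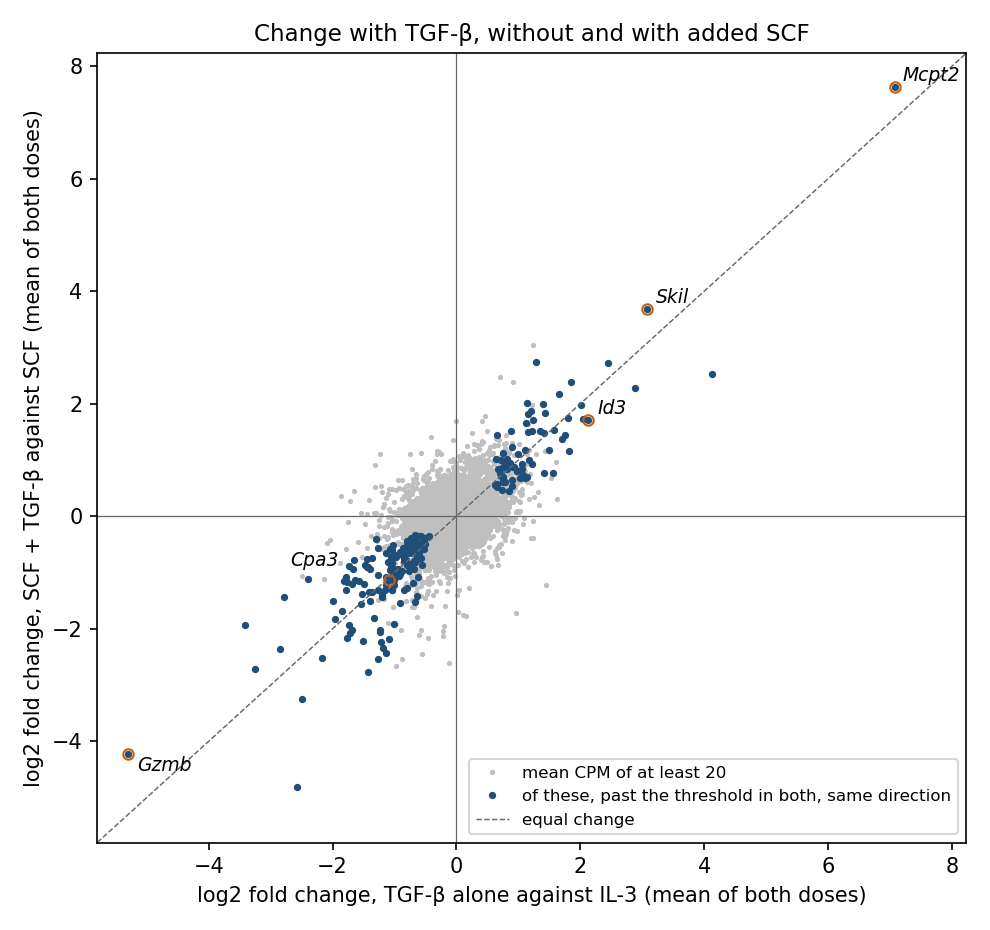
Log2 fold change with TGF-β in SCF (vertical axis, mean of both doses against SCF) against that with TGF-β alone (horizontal axis, mean of both doses against IL-3) for genes with a mean of at least 20 CPM and at least 3 CPM in the IL-3 and SCF means, blue where both passed the threshold in the same direction, with a dashed line of equal change. Mcpt2 lies at 7.08 without SCF and 7.64 with it, and Gzmb at -5.30 and -4.23.

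The reverse comparison asked what SCF added in the presence of TGF-β, as the mean of both doses with SCF (n = 4 libraries) against both TGF-β alone libraries (n = 2). Fits without a TGF-β alone library set this mean of both doses with SCF against the 1 dose left. They thus compare unlike doses and cannot tell dose from library. Mcpt1 was higher with SCF (3.74 ± 0.38, adjusted p = 7.27e-06), and the value was 2.05 without the 1 ng/mL library. Mcpt2 was higher by 1.45 ± 0.17 (adjusted p = 1.86e-05), but the value depended on the TGF-β alone library used. It was 0.09 without the 1 ng/mL library and 2.81 without the 10 ng/mL library. Mcpt4 stood at 1.67 ± 0.45 (adjusted p = 0.0121, but 0.13 without the 1 ng/mL library and 0.050 with DESeq2). Tpsab1 (3.30 ± 0.27) and Cpa3 (0.64 ± 0.10) rose, while Itgae (0.67 ± 0.37, adjusted p = 0.201), Tpsb2 (0.24 ± 0.11), Cma1 (0.11 ± 0.12), Fcer1a (-0.13 ± 0.10) and Smad7 (-0.76 ± 0.27, adjusted p = 0.0531) did not pass. Kit was at -0.34 ± 0.10 (adjusted p = 0.0216), not past the threshold without the 1 ng/mL library (0.34, value -0.20) or without 3 of the 4 SCF with TGF-β libraries (0.060 to 0.072). The mucosal list thus had 2 of 4 higher and 1 lower, as also adjusted over the list alone, the lower one being Itgb7 (-0.59 ± 0.12), which was at 0.03 without the 1 ng/mL library (adjusted p = 0.94) and -1.22 without the 10 ng/mL library. The collagen gene Col18a1 had 0 counts with TGF-β alone and was at least 149.6-fold higher with SCF, against a floor of 3 counts over the group. Tnf (3.92 ± 0.35), the serine synthesis enzyme Psat1 (3.63 ± 0.49) and the organic anion transporter Slco2b1 (3.35 ± 0.30) were also among the largest rises, and Cyp4a12a (-4.80 ± 0.28), Pigz (-4.29 ± 0.37) and Mamdc2 (-3.73 ± 0.45) among the largest falls.

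Cell cycle genes, which rose with SCF in IL-3, rose here in 35 of 36 cases (35 adjusted over the list alone), with Ccnb2 at 2.21 ± 0.22 and Mki67 at 2.23 ± 0.23. Together the cell cycle genes had a camera adjusted p = 5.69e-43, and adjusted p = 0.302 with an estimated correlation. Cholesterol synthesis genes rose in 21 of 24 (23 adjusted over the list alone), with Cyp51 at 2.04 ± 0.18 and Sqle at 1.91 ± 0.16. Together the cholesterol genes had a camera adjusted p = 5.17e-20, and adjusted p = 0.302 with an estimated correlation. Unfolded protein and amino acid response genes rose in 7 of 17 cases and fell in 1 (8 and 1 adjusted over the list alone), with the chaperone Hspa5 at 0.73 ± 0.12. Together the unfolded protein genes had a camera adjusted p = 0.0159, and adjusted p = 0.495 with an estimated correlation. No other list passed camera's test here, although single members did, and without a filter the granule list passed (camera adjusted p = 0.0290, 0.142 with it). Granule genes split 7 higher and 2 lower of 16 (8 and 3 adjusted over the list alone), with Ctsb at 1.18 ± 0.12, Gzmb at 1.94 ± 0.27 and the sulfotransferase Chst15 at -1.01 ± 0.12. Cytokine genes split 5 and 3 of 14 (6 and 3 adjusted over the list alone), with Ccl7 at 2.90 ± 0.28 and Il4 at -2.16 ± 0.28. MAPK genes split 6 and 2 of 22 (6 and 4 adjusted over the list alone), with Dusp4 at 3.27 ± 0.28 and the growth regulator Myc at 1.02 ± 0.16. STAT5 and survival genes split 2 and 4 of 15 (2 and 5 adjusted over the list alone), with Pim2 at -3.40 ± 0.34 and Il2ra at -2.02 ± 0.30. Glycolysis and hypoxia genes split 9 and 4 of 23 (10 and 5 adjusted over the list alone), with Pkm at 0.96 ± 0.13 and Ndrg1 at -2.45 ± 0.19. Glycan transfer genes had 1 higher and 6 lower of 22 (2 and 9 adjusted over the list alone), with St3gal1 at -1.87 ± 0.23. For connective tissue genes the split was 3 and 1 of 10 (3 and 2 adjusted over the list alone), for identity genes 2 and 3 of 16 (2 and 3) and for TGF-β response genes 3 and 5 of 21 (3 and 8). It was, for eicosanoid genes, 3 higher of 11 (3), for integrins 2 and 2 of 12 (3 and 3) and for interferon genes 1 and 1 of 12 (1 and 1), each with the count adjusted over the list alone in brackets. The fit without SCF replicate 1, SCF replicate 2 or replicate 1 of SCF with 10 ng/mL called 4 MAPK genes lower. Without replicate 2 of SCF with 10 ng/mL edgeR called 3 cytokine genes higher. Leaving out the 1 ng/mL library gave 3 unfolded protein and 3 cytokine genes higher and 3 TGF-β response genes lower. The fit without the 10 ng/mL library called 4 unfolded protein and 2 cytokine genes higher and 3 glycan genes lower. A total of 2780 genes passed, 1500 higher and 1280 lower, 1340 of them at least 2-fold. DESeq2 called 1518, and the count was 1278 without the 1 ng/mL library and 1802 without the 10 ng/mL library.

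Whether SCF altered the response to TGF-β was tested directly, as the difference on the log2 scale between the TGF-β effect with SCF and without it. Neither Mcpt2 (0.55 ± 0.41, adjusted p = 0.730) nor Mcpt1 (1.44 ± 5.01, adjusted p = 0.962) showed a difference past the threshold. Neither value was stable: without the 1 ng/mL TGF-β library both turned (-0.81 and -0.29), and without the 10 ng/mL library they were 1.91 and 3.10. Without SCF replicate 1 or 2, Mcpt1 was at 3.74 or 0.74. No difference past the threshold was seen either for Itgae (0.77 ± 1.76), Mcpt4 (-0.36 ± 0.81), Cma1 (0.08 ± 0.18), Cpa3 (-0.06 ± 0.15), Kit (-0.16 ± 0.16), Fcer1a (-0.15 ± 0.15) and Smad7 (-0.66 ± 0.65). Signs turned for Itgae without IL-3 replicate 2 (-3.01), Mcpt4 without IL-3 replicate 1 (0.07) or SCF replicate 2 (0.32), and Cma1 without SCF replicate 2 (-0.06) or replicate 1 of SCF with 10 ng/mL (-0.00442). Cpa3 turned without SCF replicate 1 (0.04) or replicate 2 of SCF with 1 ng/mL (0.02). For Mcpt1 the standard error was too wide for any such difference to be detectable at this depth. Tpsb2 was the anchor gene that passed (-0.83 ± 0.17, adjusted p = 0.0497), and it was not past the threshold in 10 of its alternatives (adjusted p = 0.050 to 0.21). Genes that passed included the tumor necrosis factor family ligand Tnfsf14 (2.10 ± 0.29, adjusted p = 0.00686, but 0.060 without IL-3 replicate 1 and 0.10 without the 10 ng/mL TGF-β library) and Ndrg1 (-1.92 ± 0.27, adjusted p = 0.00686, but 0.060 without IL-3 replicate 1 and 0.070 without the 1 ng/mL TGF-β library). Cell cycle genes had positive interaction values in 35 of 36 cases with no single member past the threshold (6 higher at an unadjusted p under 0.05), and cholesterol synthesis genes in 21 of 24 (none past the threshold, 1 adjusted over the list alone, 6 at an unadjusted p under 0.05). For the cell cycle interaction camera gave adjusted p = 1.52e-05, and adjusted p = 0.717 with an estimated correlation. For the cholesterol interaction camera gave adjusted p = 0.00850, and adjusted p = 0.717 with an estimated correlation. Single members past the threshold over all genes were Tpsb2 in the connective tissue list (2 lower adjusted over the list alone; camera adjusted p = 0.0526) and the lysosomal protease Ctsd (-0.92 ± 0.15) in the granule list (2 higher and 1 lower adjusted over the list alone). Ctsd was not past the threshold without IL-3 replicate 1 (adjusted p = 0.11) and in 4 other fits without 1 library (0.056 to 0.075). The third such member was Ndrg1 in the glycolysis list (2 lower adjusted over the list alone). The other lists did not pass camera's test. Adjusted over the list alone they held 1 lower mucosal gene, 1 lower eicosanoid gene, 2 higher cytokine genes, 2 lower TGF-β response genes, 2 lower integrins, 1 higher MAPK gene and 1 lower glycan gene. A total of 33 genes passed, 13 higher and 20 lower. The count was 0 in edgeR's test without IL-3 replicate 1 (891 at an unadjusted p under 0.05) and 9 without IL-3 replicate 2. It was 11 without SCF replicate 1, 19 without replicate 2 of SCF with 1 ng/mL TGF-β, 17 and 9 without replicate 1 and 2 of SCF with 10 ng/mL, 3 and 15 without the 1 and 10 ng/mL TGF-β libraries. The count was 69 without the second libraries of the SCF-containing groups and 125 with no filter, and DESeq2 called 22 and limma-voom 33.

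Markers of other blood cells and of RNA quality were followed alongside. No listed neutrophil or fibroblast marker reached the counts needed for testing. With SCF the macrophage marker Cd68 rose (4.23 ± 0.52) and the fractalkine receptor Cx3cr1 fell (-1.61 ± 0.25), 1 higher and 1 lower of 5 macrophage markers (1 and 1 adjusted over the list alone). Against TGF-β alone, SCF with TGF-β gave the same pair of changes (2.91 ± 0.44 and -2.003 ± 0.20; 1 and 2 adjusted over the list alone). The lysozyme gene Lyz2 fell with 10 ng/mL TGF-β in SCF (-3.54 ± 0.64; 1 higher and 1 lower of that list adjusted over the list alone). At 1 ng/mL no macrophage marker passed (1 lower adjusted over the list alone), and with TGF-β alone Cx3cr1 was higher (0.98 ± 0.24, 1 of 5; 1 adjusted over the list alone). It was not past the threshold without IL-3 replicate 1 or 2 (adjusted p = 0.218 and 0.135) or without the 1 or 10 ng/mL library (0.0634 and 0.146). Basophil markers had 2 higher and 1 lower of 5 with SCF (2 and 2 adjusted over the list alone), 1 lower with 1 ng/mL TGF-β in SCF (2 higher and 1 lower adjusted over the list alone), 1 lower with 10 ng/mL (1 and 2). With SCF only Cpa3, which is also a mast cell gene, passed without IL-3 replicate 1 or 2 or SCF replicate 1 or 2: Mcpt8 had adjusted p = 0.251, 0.153, 0.121 and 0.130, and Prss34 0.0853, 0.156, 0.162 and 0.0923. Cpa3 was also the lower marker at each dose in SCF. The basophil list had 2 lower with TGF-β alone (2), Cpa3 (-1.08) and Cyp11a1 (-0.60). Camera placed the list lower there (adjusted p = 0.00132, 0.202 with an estimated correlation, 0.0833 without a filter). With SCF added to TGF-β 3 were higher (3), Cpa3 among them. Since Cpa3 is a mast cell gene too, these counts do not show a change in basophils. The integrin chain Itgax, a dendritic cell marker, had pooled count ratios of 43.9-fold (95% counting interval 7.53 to 1769) with 10 ng/mL TGF-β in SCF and 48.3-fold (95% counting interval 12.9 to 407) with TGF-β alone, 1 of 2 tested dendritic markers in each case. Its fitted value with TGF-β alone, 5.31, became 8.51 without IL-3 replicate 1. With 1 ng/mL TGF-β in SCF it was 1 higher marker and 1 other was lower adjusted over the list alone, and with SCF added to TGF-β 1 was lower. Eosinophil markers had 1 and 2 of 3 lower with 1 and 10 ng/mL TGF-β in SCF (2 and 2 adjusted over the list alone; camera adjusted p = 0.0460 and 0.0494 without a filter), 2 lower with SCF added to TGF-β (2) and none past the threshold with SCF or with TGF-β alone (0 and 0 lower at an unadjusted p under 0.05). The 2 tested lymphocyte markers passed only with SCF added to TGF-β, 1 higher and 1 lower (1 and 1 adjusted over the list alone; 1 higher adjusted over the list alone with SCF and 1 with TGF-β alone). Of 4 erythroid and platelet markers none passed in any of the 7 comparisons, nor did any at an unadjusted p under 0.05. In the interaction no marker passed, and adjusted over the list alone 1 eosinophil and 1 lymphocyte marker were lower. Of the 8 RNA quality and stress genes 1 rose and 1 fell with SCF (1 and 1 adjusted over the list alone), and 2 rose and 3 fell with SCF added to TGF-β (2 and 3), including the nuclear RNA Malat1 (-0.76 ± 0.10) and the chaperone Hspa8 (0.60 ± 0.12). The nuclear RNA Neat1 fell with 10 ng/mL TGF-β in SCF (-0.77 ± 0.13, 1 lower adjusted over the list alone), 1 was lower at 1 ng/mL (1) and none passed with TGF-β alone (2 lower at an unadjusted p under 0.05).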

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

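The tests of technical explanations in this part were all chosen after the results they examine had been seen, while the interaction itself and its gene lists were planned.

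The effect of TGF-β differed with and without SCF in a test of the difference itself for 33 genes. Higher with SCF on the log2 scale were Tnfsf14 (2.10), Raly (2.23), Rnf187 (2.23), Atad3a (1.98), Kif23 (1.86), Endod1 (1.82), Lsm4 (1.76) and Spi1 (1.62). Lower were Tpsb2 (-0.83), Ndrg1 (-1.92), Ctsd (-0.92), Btg2 (-2.67), Gpx3 (-2.67), Asphd2 (-2.48), Trpm2 (-2.31), Dlg2 (-2.20), Ntng2 (-1.83) and Fgd2 (-1.75). The cell cycle and cholesterol synthesis lists differed by camera (adjusted p = 1.52e-05 and 0.00850, each 0.717 with an estimated correlation).

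These 33 genes are the first pattern weighed. Uneven reads from ribosomal RNA and satellite loci cannot be told apart from an effect of the groups. Without those loci 31 of the 33 genes kept their call, but so did 97.5% to 100% of the genes in the other 6 comparisons, so the removal tests little. Low depth of the TGF-β alone libraries cannot be told apart either. The genes had a median mean CPM of 76.3 (quartiles 35.2 and 166), against 44.1 (17.8 and 104) for the 3463 genes called in another comparison, and these ranges overlap. A part played by IL-3 replicate 1 cannot be told apart from an effect of the groups, because without it 0 genes were called by edgeR (33 of these 33 at an unadjusted p under 0.05), with a median size of 1.54 instead of 1.72, a median standard error of 0.338 instead of 0.313 and 3 residual degrees of freedom instead of 4. With these explanations open, no biological one is put forward for the 33 genes.

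The second pattern is Mcpt2 in the wells without added SCF. RNA or reads from wells that held SCF are argued against as the whole cause at 10 ng/mL only. In the 10 ng/mL library, 168 genes raised by SCF reached a median of 17.3% of their rise above IL-3 with SCF and TGF-β (quartiles 0.667% and 28.7%), against 73.8% for Mcpt2, and 2 of them reached at least the share of Mcpt2. In the 1 ng/mL library, 175 such genes reached a median of -1.81% (quartiles -11.5% and 5.05%), against 17.9% for Mcpt2. Of these genes, 19 reached at least that share. TGF-β alone lowered some genes that SCF raised, such as Sqle, Slc2a3 and Ccl7, which could hide such reads. They thus stay open for the 1 ng/mL library. Reads of the paralog Cma1 are argued against too, with at least 3.24 Mcpt2 counts per 100 Cma1 counts in these libraries against 0.0389 and 0.0569 with IL-3. The rise was called in every fit without 1 library, and Mcpt2 also rose with TGF-β in SCF, by 7.29 and 7.98 on the log2 scale, in other libraries. That TGF-β raises Mcpt2 without added SCF is put forward for 10 ng/mL, as a hypothesis since it was found and tested on the same data.

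The third pattern is Mcpt1 relative to Mcpt2. Libraries with SCF and TGF-β had 2.21 to 3.15 Mcpt1 counts per 100 Mcpt2 counts, those with TGF-β alone 0.421 and 0.684. Misassigned Mcpt2 reads are argued against as the whole source of Mcpt1 with SCF and TGF-β, since the highest upper 95% limit without SCF, 1.24, lay below the lowest value with SCF. For Mcpt1 with TGF-β alone they stay open, because the 95% intervals of the 2 libraries, 0.0867 to 1.24 and 0.476 to 0.952, overlap. RNA or reads from wells that held SCF were not tested as a source of Mcpt1 there. Whether SCF itself favours Mcpt1 stays a hypothesis, untested beyond these libraries.

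Outside the gene counts, reads without a feature were above the IL-3 libraries (31.7% and 28.8%) in SCF replicates 1 (33.6%) and 2 (33.03%), SCF with 1 ng/mL TGF-β replicates 1 (32.4%) and 2 (33.01%) and SCF with 10 ng/mL TGF-β replicate 1 (32.9%). Ambiguous reads were above IL-3 (2.65% and 2.54%) in replicate 2 of SCF (2.83%) and replicate 2 of SCF with 1 ng/mL TGF-β (2.85%). Reads not uniquely aligned were above IL-3 (42.7% and 48.8%) with 1 ng/mL TGF-β alone (55.6%).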

How the results depend on the processing

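The alternatives were chosen before the data were examined, except the fits without ribosomal RNA and satellite loci, without both TGF-β alone libraries, without the second libraries of the 3 SCF-containing groups and with each dose against its own SCF library, which were chosen after. Of 409 results for named genes, 367 were past the threshold, and these gave 7128 values under alternatives: 6598 kept direction and threshold, 529 kept the direction only and 1 turned. Of the 367, 233 were past the threshold in every alternative that gave a value and 239 in every fit without 1 library. The other results gave 804 values, of which 39 came past the threshold and 34 turned without passing it. DESeq2 gave no adjusted p for 38 values, and 10 values were absent under a filter. A fit without 1 library leaves some groups with 1, which is assumed to vary like the others, and fewer samples also widen the errors. Without a TGF-β alone library the dose left stands for both, while the side with SCF keeps the mean of both doses. The interaction has no fit of only the groups compared, since every group enters it. Elsewhere the cause was not tested. Counts are given in the order SCF against IL-3, SCF with 1 ng/mL TGF-β against SCF, SCF with 10 ng/mL against SCF, the 2 doses, TGF-β alone, SCF added to TGF-β, and interaction; the counts in full are 1031, 522, 941, 2, 391, 2780 and 33. With a 2-fold threshold they were 506, 287, 510, 2, 228, 1340 and 29. DESeq2 gave 471, 270, 438, 0 (46 at an unadjusted p under 0.05), 225, 1518 and 22. For the doses limma-voom gave 0 (306 unadjusted), as did edgeR with the 10 CPM filter (235), the 2 groups alone (258) and both TGF-β alone libraries left out (284). No filter gave 8 for the doses, 601 for TGF-β alone and 125 for the interaction, and only the groups compared gave 712 for TGF-β alone. Without the second libraries the counts were 594, 289, 559, 8, 683, 2163 and 69. With each library left out in turn the counts were 237 to 1055, 252 to 540, 447 to 952, 0 to 5, 143 to 442, 1278 to 2799 and 0 to 30, with 0 in edgeR's test for the doses without replicate 1 of SCF with 1 ng/mL (366 unadjusted) or 10 ng/mL TGF-β (278) and for the interaction without IL-3 replicate 1 (891). Replicate deviations correlated at 0.326 to 0.368 among the SCF-containing groups and at -0.00947 to 0.00351 between them and IL-3 over 7166 genes. Libraries of the same number thus deviated together in the SCF-containing groups, beyond the 0.1 set as needed for a pairing. With IL-3 they did not over these 7166 genes, although 8 of 8 immediate early genes were higher in replicate 1 there too. The labels do not say what the number marks, so the pairing stays undecided and the main fits left it out. The replicate block gave 859 for 1 ng/mL in SCF, 5 for the doses, 718 for TGF-β alone and 102 for the interaction, and stayed within 1.5 times for the others. With it camera no longer passed the MAPK list for SCF against IL-3 (adjusted p = 0.124). It newly passed the connective tissue list, lower, with 1 ng/mL in SCF (adjusted p = 0.0192, 0.124 without the block) and in the interaction (0.0105, 0.0526 without). Newly past were also the MAPK list, higher, between the doses (0.00660, 0.0910 without) and the glycan list, lower, for SCF added to TGF-β (0.0485, 0.0531 without). The 479 genes called at both doses were 241 and 202 with each dose against its own SCF library.

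With an estimated correlation camera passed 0 lists in each of the 7 comparisons. Without a filter it passed 6 of the 10 lists for SCF against IL-3 and no other. For the doses it passed 2 of the 6 lists, TGF-β response and cholesterol, and the mucosal list, which had too few tested members under the filter, for 3 in all. The mucosal list also passed for both doses in SCF (0.00911 and 0.00744) and TGF-β alone (0.0253), the eosinophil list for both doses (0.0460 and 0.0494) and the granule list for SCF added to TGF-β (0.0290). The glycan list at 1 ng/mL (0.116) and the basophil list with TGF-β alone (0.0833) no longer passed, and no other list changed its call. The correlation of TGF-β effects with and without SCF was 0.441 over all genes, 0.614 at a mean of at least 20 CPM, 0.280 for the 1 ng/mL library and 0.427 for the 10 ng/mL library. Signs turned for these log2 values, all but 1 not past the threshold. Itgae for SCF against IL-3 was 0.65 with limma-voom and 0.15 without the second libraries, and its interaction -0.0669 with limma-voom. Kit between the doses was 0.000736 with the 10 CPM filter, and the Mcpt4 interaction 0.11 without the second libraries. Ranges over the fits without 1 library were, for SCF against IL-3, Mcpt1 0 to 3.02, Cma1 -0.14 to 0.19, Itgae -1.26 to 3.70, Fcer1a -0.0398 to 0.0866 and Smad7 -0.54 to 0.37; Tpsb2 in SCF -0.17 to 0.11 at 1 ng/mL and -0.20 to 0.0747 at 10 ng/mL. Between the doses they were Mcpt4 -0.62 to 0.36, Cma1 -0.19 to 0.15, Tpsb2 -0.16 to 0.11 and Kit -0.0534 to 0.0407. For SCF added to TGF-β, Itgb7 ranged from -1.22 to 0.0271, the exception that was called. For the interaction they were Mcpt1 -0.29 to 3.74, Mcpt2 -0.81 to 1.91, Mcpt4 -0.87 to 0.32, Cma1 -0.0581 to 0.25, Cpa3 -0.13 to 0.0405 and Itgae -3.01 to 1.95. Depth limited Mcpt1, with 0 counts in IL-3 and 1 in SCF, and Itgae, with 3 counts in each.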

Other observations

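The genes in this part were chosen after their values had been seen, and no explanation was tested for them. The chemokine receptor Ccr1 rose with SCF (1.24 ± 0.19) and fell with 10 ng/mL TGF-β in SCF (-2.04 ± 0.20) and with TGF-β alone (-1.85 ± 0.26). The histamine receptor Hrh4 fell with TGF-β in SCF (-1.43 ± 0.22 and -1.80 ± 0.23). The aggrecan-degrading protease Adamts5 rose with TGF-β in SCF (2.34 ± 0.31 and 2.72 ± 0.30) and with TGF-β alone (4.12 ± 0.28), and fell when SCF was added to TGF-β (-1.70 ± 0.18). The related protease Adamts1 rose with TGF-β alone (3.78 ± 0.60). Collagen Col18a1 rose further with TGF-β in SCF (3.11 ± 0.28 and 3.40 ± 0.28), and had pooled counts of 68 with SCF against 1 with IL-3, a ratio of 63.6-fold (95% counting interval 11.1 to 2551). Cd24a, which SCF lowered (-3.44 ± 0.37), rose with TGF-β in SCF (2.63 ± 0.40 and 2.34 ± 0.41).

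The lysophosphatidic acid receptor Lpar6 fell with SCF (-1.15 ± 0.19) and with SCF added to TGF-β (-1.79 ± 0.16), as did the endothelin receptor Ednra in the second case (-3.67 ± 0.38). The transcription factor Batf fell with 10 ng/mL TGF-β in SCF (-1.26 ± 0.22), and Stat5a, which transmits IL-3 signals, fell with SCF added to TGF-β (-1.03 ± 0.16). In the 6 comparisons of groups every named gene that was called had all libraries of one side beyond those of the other, except Mcpt2 and Itgb7 for SCF added to TGF-β. For the largest changes the rule for naming genes required this. Nearly all called genes met it too: 1031 of 1031, 522 of 522, 940 of 941, 2 of 2, 390 of 391 and 2731 of 2780. It therefore does not set the named genes apart.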
